A study of Mus musculus with 9 samples.

How the data were processed

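The series measured gene expression in mouse heart by RNA sequencing of 9 libraries. Per the labels' protocols, total RNA was extracted with Trizol, poly(A) RNA was selected, and paired-end libraries were sequenced on an Illumina NovaSeq instrument. The labels' protocol also speaks of an adipose type, although the source of all 9 samples is given as heart. The deposited table holds whole-number counts for 55401 Ensembl genes, with 1 column per library, per the file headers, and the counts are not scaled for depth or gene length. Per the submitters' processing notes, Bowtie 0.12.2, HISAT2 2.0 and StringTie 1.3.0 were used with the genome build mm8. The notes give neither their roles nor their order, and the counting step, annotation release and strand setting are not given in the sources used here. Counts made with StringTie can be derived from coverage, which would leave them close to read counts but not equal to them.

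Groups followed the treatment label: Ctrl, AngII and Kmo_AngII, with 3 libraries each. Replicate numbers within a group were given in sample order and pair nothing. A second grouping used the letters at the start of the sample title (WC, WA and KKA, 3 libraries each), because these letters cross the treatment labels. No sample was moved between groups on account of its values. The total count per library ranged from 56827533 to 73194268. No pair of libraries agreed within counting noise, since the lowest chi-square per degree of freedom between libraries was 62.1. Gene symbols were taken from a table of gene identifiers and matched 55141 of the 55401 genes, and the other 260 kept their identifier. No coordinates are given, because the reference used for symbols is of another build than mm8.

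Differences between groups were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with robust dispersion estimates, TMM normalisation and the filter of filterByExpr, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. All 9 libraries entered 1 fit per grouping, for 6 comparisons, and an adjusted p under 0.05 was a call. A log2 difference is the first group minus the second and is given with a standard error. That standard error was derived from the fitted difference and its F statistic, so it restates the test and is not a separate measure of precision. Normalised counts are given as CPM, counts scaled to the library size, and use TMM library sizes. Principal components were computed on log2 CPM with a prior count of 2. The fit of only the WA and WC libraries was planned as an alternative and is reported as a result of its own, because its count departed from that of the fit of 9 libraries. Its own alternatives were added after the data were seen. The share of counts from mitochondrially encoded and haemoglobin genes was compared by two-sided exact permutation tests.

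A total of 45 gene lists were fixed before the data were examined, for heart muscle, matrix, metabolism, protein turnover, stress and the cell types that a heart sample can hold. Each list with at least 3 tested genes was tested with limma 3.58.1 by camera on voom values, with a preset correlation between genes of 0.01, and adjusted over the lists of a comparison. Beside it stand camera with an estimated correlation and fry. Camera sets a list against the other genes, and fry tests whether the genes of a list move on balance in 1 direction. Counts of called members are given over all genes tested and adjusted over the list alone. Some lists share genes, so the calls of different lists are not all separate findings.

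Genes were named by a rule fixed before the data were examined. It takes 16 index genes. It then takes the 10 highest and 10 lowest log2 differences among called genes that have a mean log2 CPM of at least 1 and no overlap between groups, leaving out gene models without an established symbol. It takes last up to 4 called members of each list by p, or the member with the smallest p where none is called. The report gives only part of the genes that the rule names. Genes outside the rule are said to have been chosen after their values were seen. The alpha haemoglobin genes, the beta haemoglobin genes, Hspa1a and the mitochondrially encoded genes share sequence with near-identical copies, so their values are uncertain.

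Alternatives were DESeq2 size factors, library size as the only scaling, no low-count filter, a filter of at least 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, fitting only the groups compared, leaving out mitochondrially encoded, haemoglobin and Nppa genes, leaving out each library in turn, and the other grouping as a covariate. The fits were tested on simulated data in which 200 genes were changed, beside a further list of genes raised 2-fold. All of these were drawn from genes with many counts, so the recovery does not hold for genes with few counts. Simulated counts were drawn independently for each gene. The recovery and the calls of unchanged genes therefore do not show how the fits behave where many genes of a library shift together. For AngII minus Ctrl, with 18364 genes, edgeR recovered 4% of 2-fold and 67% of 4-fold changes and called 5 unchanged genes. For WA minus WC with all 9 libraries, with 18512 genes, it recovered 8% and 74% and called 4 unchanged genes. For the 6 WA and WC libraries alone, with 17489 genes, it recovered 43% and 90% and called 13 unchanged genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.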

Results

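Poly(A) RNA from hearts of C57BL/6 mice, an inbred laboratory strain, was sequenced in 9 libraries. The treatment labels form 3 groups of 3 libraries. Ctrl hearts came from mice given PBS, a salt buffer. AngII hearts came from mice given angiotensin II, a peptide hormone that raises blood pressure. Kmo_AngII hearts also came from mice given angiotensin II, and the labels do not explain what Kmo stands for. The sample titles give a second grouping, by the letters WC, WA or KKA, which are not explained either. The titles also hold a number after these letters, whose meaning is not given. WC marks the libraries labelled Ctrl replicate 1, AngII replicate 1 and AngII replicate 2. WA marks those labelled Ctrl replicate 2, Ctrl replicate 3 and AngII replicate 3, and KKA marks the 3 libraries labelled Kmo_AngII. The total count per library ranged from 56827533 to 73194268, and 19091 of the 55401 genes had enough counts to be tested. No label says that the libraries of a group came from separate animals, so each p-value measures the spread between these samples, which may be technical.

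The first principal component of log2 CPM (counts scaled to library size) held 30.4% of the variance, and the libraries did not lie by treatment label on it. On it, the 3 libraries titled WA and the library labelled Kmo_AngII replicate 1 lay between 44.4 and 65.3. The 3 libraries titled WC and the libraries labelled Kmo_AngII replicates 2 and 3 lay between -77.3 and -30.7. By full title, the first side held WA_127, WA_130, WA_132 and KKA_K084. The other side held WC_3, WC_182, WC_184, KKA_186 and KKA_187. The title numbers were looked at after the values were seen, and a grouping by them was not tested. On the second component (17.9% of the variance) the libraries labelled Kmo_AngII replicate 3 and Ctrl replicate 2 lay at 80.7 and 56.2, and the other 7 between -47.2 and 12.7. There the 3 libraries labelled AngII (-47.2 to -15.1) all lay below the 3 labelled Ctrl (-9.27 to 56.2). Pearson correlations between libraries, computed across genes, ranged from 0.909 to 0.967. Acta1, which encodes skeletal alpha-actin and is raised in hypertrophic heart muscle, followed the division on the first component. Its normalised level was 686 and 678 CPM in the libraries labelled Ctrl replicates 2 and 3, 617 in AngII replicate 3 and 633 in Kmo_AngII replicate 1. In the other 5 libraries it lay between 11.3 and 39.6.

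**Figure D1:**
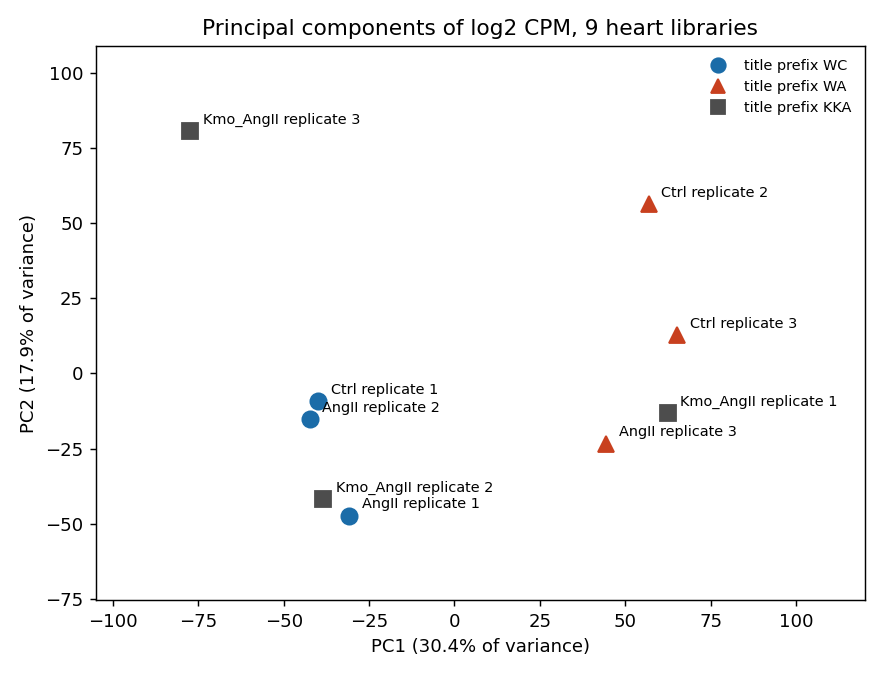
Each point is 1 of the 9 libraries, named by treatment label and replicate, on the first (30.4% of the variance) and second (17.9%) principal components of log2 CPM. Colour and shape give the title prefix, and the 3 WA libraries and Kmo_AngII replicate 1 lie between 44.4 and 65.3 on the first component.

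The study concerns JOSD2, a deubiquitinase, and SERCA2a, the calcium pump of the sarcoplasmic reticulum, which Atp2a2 encodes. Josd2 (ENSMUSG00000038695) had 50.1 ± 3.88 CPM in Ctrl, 56.4 ± 10.0 in AngII and 49.6 ± 15.9 in Kmo_AngII (SD, n = 3 each). Its lowest value was 31.8, in the library labelled Kmo_AngII replicate 3. The log2 difference of Josd2 was 0.17 ± 0.27 (SE) for AngII minus Ctrl (edgeR adjusted p = 0.955) and -0.18 ± 0.27 for Kmo_AngII minus AngII (edgeR adjusted p = 0.9998). Atp2a2 (ENSMUSG00000029467) had 2450.3 ± 1206 CPM in Ctrl, 1789.6 ± 740.5 in AngII and 2119.8 ± 1651 in Kmo_AngII (SD, n = 3 each). Its log2 difference was -0.45 ± 0.61 for AngII minus Ctrl (edgeR adjusted p = 0.945) and 0.24 ± 0.61 for Kmo_AngII minus AngII (edgeR adjusted p = 0.9998). Neither direction held under all alternatives, since the first was 0.22 with library size as the only scaling, and the second was -0.62 without Kmo_AngII replicate 1 and -0.01 without AngII replicate 2. The Josd2 difference for Kmo_AngII minus AngII was 0.05 without Kmo_AngII replicate 3. Kmo (ENSMUSG00000039783), which encodes kynurenine 3-monooxygenase and shares its symbol with the group label, was low in every library, at 21 to 102 raw counts. It had 0.924 ± 0.0669 CPM in Ctrl, 0.890 ± 0.559 in AngII and 0.540 ± 0.281 in Kmo_AngII (SD, n = 3 each). Per library, the Kmo_AngII values of Kmo were 0.299, 0.473 and 0.849, and AngII replicate 1 had 0.247. The log2 difference of Kmo was -0.73 ± 0.62 for Kmo_AngII minus AngII (edgeR adjusted p = 0.9998). It was -0.78 ± 0.62 for Kmo_AngII minus Ctrl (edgeR adjusted p = 0.998) and -0.97 ± 0.59 for KKA minus WA (edgeR adjusted p = 0.741), and in both of these every Kmo_AngII library lay below every library of the other group, which chance gives 5% of genes in this direction. No comparison called Kmo.

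**Figure D2:**
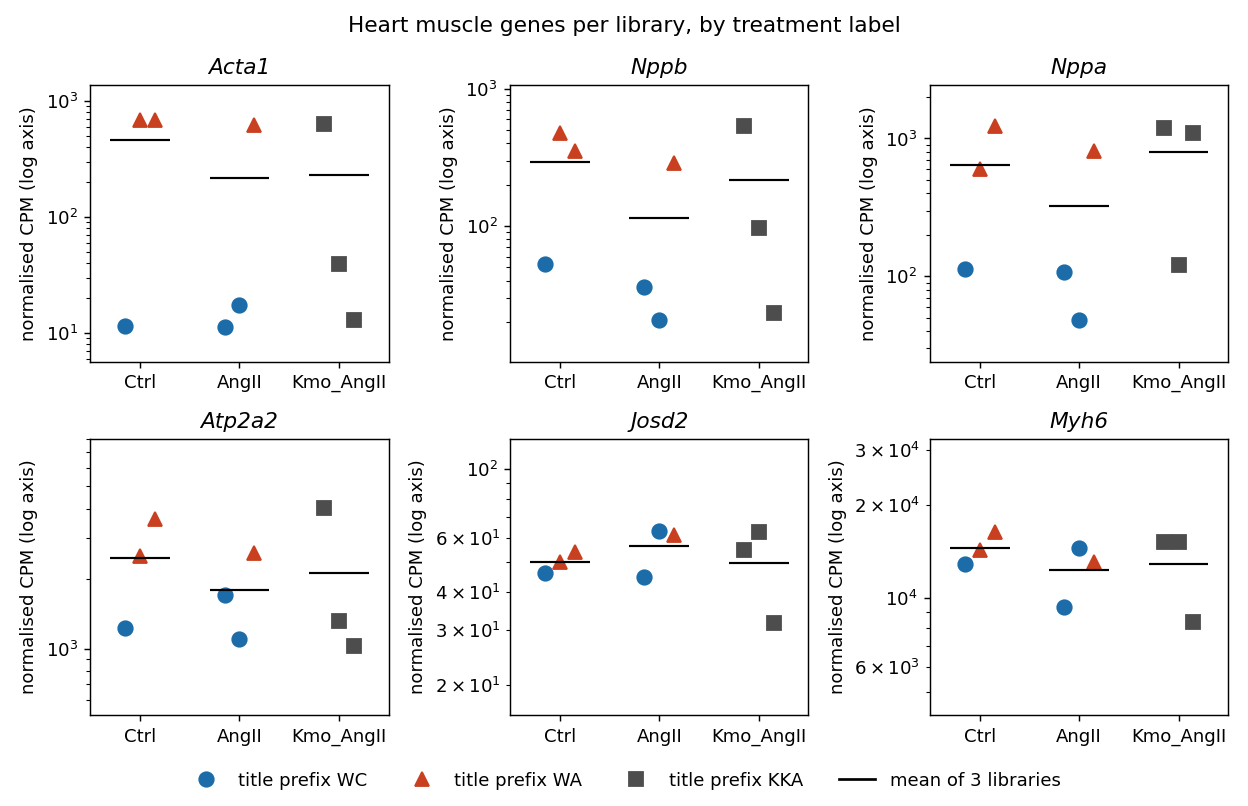
Normalised CPM (log axis) of 6 genes fixed in advance, with 1 point per library, by treatment label. Colour and shape give the title prefix, and a line gives the mean of 3 libraries. Josd2 lies between 31.8 and 62.8 in all 9 libraries, whereas Acta1 is 617 to 686 in the 4 libraries made up of WA and Kmo_AngII replicate 1.

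AngII minus Ctrl asks what angiotensin II changed in the heart. With edgeR, 0 of 19091 genes passed an adjusted p of 0.05, 1003 had an unadjusted p under 0.05 and the smallest adjusted p was 0.890. DESeq2 called 2 genes, Olfr77 and Gm16701, and limma-voom called 0. A single gene passed in edgeR without Ctrl replicate 1 (Cyren, adjusted p = 0.0244), without AngII replicate 2 (Lin52, adjusted p = 0.0145) and without AngII replicate 3 (Gm10774, adjusted p = 0.0237). These 5 genes were chosen after their values were seen. The hypertrophy markers were not higher in the libraries labelled AngII. Nppa, which encodes atrial natriuretic peptide, had a log2 difference of -1.01 ± 1.14 (SE; edgeR adjusted p = 0.934), and Nppb, which encodes the brain natriuretic peptide, one of -1.36 ± 1.23 (adjusted p = 0.915). Acta1 had -1.09 ± 1.77 (adjusted p = 0.957), and the myosin genes Myh6 and Myh7 had -0.24 ± 0.40 (0.960) and -0.63 ± 0.38 (0.890). Of the remaining index genes, Pln, Col1a1, Col3a1, Postn, Ccn2, Agtr1a and Timp1 had negative log2 differences, from -1.29 ± 0.68 for Timp1 to -0.12 ± 0.76 for Col3a1, and Ryr2 had 0.06 ± 0.37 (adjusted p from 0.890 to 0.990). Over the alternatives Nppa ranged from -3.06 (without AngII replicate 3) to -0.16 (without Ctrl replicate 3), Nppb from -3.37 (without AngII replicate 3) to -0.63 (library size as the only scaling) and Acta1 from -4.99 (without AngII replicate 3) to 0.10 (title prefix as a covariate), and Myh6, Myh7, Col3a1 and Ryr2 also changed sign. With the title prefix as a covariate edgeR again called 0 genes, with 1696 at an unadjusted p under 0.05.

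Gene lists fixed in advance were compared between AngII and Ctrl with limma camera, which asks whether a list moves further than the other genes. The camera test called 8 of 45 lists. The strongest call was for the 13 mitochondrially encoded genes, all 13 lower in AngII, with a median log2 difference of -1.36 (adjusted p = 1.01e-11). The adjusted p of all 8 called lists was 0.889 with an estimated correlation, and fry, which tests each list by itself, gave 0.940. No member of these lists passed in edgeR, over all genes or adjusted over the list alone, and mt-Atp8 had the smallest p among the mitochondrial members, with a log2 difference of -1.85 ± 0.63 (SE; adjusted p = 0.890). Mitochondrially encoded genes took 48.1% ± 4.62 of the counts in Ctrl, 33.9% ± 4.87 in AngII and 42.5% ± 12.5 in Kmo_AngII (SD, n = 3 each). The AngII and Ctrl shares did not overlap (two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries can give). With library size as the only scaling the median of all genes shifted from 0.02 to 0.67, and the mitochondrial list then had a median of -0.68, or -1.35 relative to all genes. The fetal and hypertrophy list was lower in AngII (median -0.79, adjusted p = 0.00295), a call that was lost without Ctrl replicate 2 (0.113) or AngII replicate 2 (0.0955). The call was kept with the title prefix as a covariate. The sarcomere list was also lower (median -0.48, adjusted p = 0.00228; 0.0590 without Ctrl replicate 3), but its median was 0.20 with library size as the only scaling, or -0.47 relative to all genes. The calcium handling list was not called (adjusted p = 0.0810).

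Kmo_AngII minus AngII asks what the unexplained Kmo condition changed under angiotensin II. With edgeR, 0 of 19091 genes passed, 412 had an unadjusted p under 0.05 and the smallest adjusted p was 0.9998. DESeq2 called 3 gene models (Gm49394, Gm47204 and 1010001B22Rik), limma-voom called 0, and edgeR called only Lin52 without AngII replicate 2 (adjusted p = 0.0200) and only Gm10774 without AngII replicate 3 (adjusted p = 0.0207). These 5 genes were chosen after their values were seen. Nppa differed by 1.32 ± 1.15 on the log2 scale (SE), Nppb by 0.93 ± 1.22 and Acta1 by 0.09 ± 1.75, each with an edgeR adjusted p of 0.9998. These 3 values depended on single libraries: Nppb was -0.93 and Acta1 -3.04 without Kmo_AngII replicate 1, Nppb was 2.95 and Acta1 3.99 without AngII replicate 3, and Nppa ranged from 0.81 (without AngII replicate 2) to 3.37 (without AngII replicate 3). The matrix genes Timp1 and Col1a1 differed by 2.04 ± 0.69 and 1.45 ± 0.68 (adjusted p = 0.9998), but by 1.03 and 0.09 without Kmo_AngII replicate 3. Camera called immune cell lists higher in Kmo_AngII, not all of them in every library. Of the macrophage and monocyte markers 25 of 26 had a positive difference (median log2 difference 0.81, adjusted p = 7.26e-12), and of the T and NK cell markers 19 of 20 (median 0.97, adjusted p = 1.27e-11). The antigen presentation list (12 of 15 positive, median 0.65) and the cytokine and chemokine list (23 of 28 positive, median 0.75) had adjusted p = 1.06e-06 and 2.75e-05. The mean level of the T and NK cell list, relative to the 9 libraries on the log2 scale, was 0.73 to 0.76 in the Kmo_AngII libraries and -0.74 to 0.31 in AngII. The macrophage level was 0.68 and 0.91 in Kmo_AngII replicates 2 and 3 but -0.32 in replicate 1, below the -0.01 and -0.04 of AngII replicates 1 and 2. The cytokine level was likewise 0.67 and 1.18 but -0.23 in replicate 1, against -0.01 and 0.03, so replicates 2 and 3 carried both of these calls. For these 4 lists the adjusted p was 0.842 with an estimated correlation, and 0 members passed in edgeR, over all genes or adjusted over the list alone. Cd74, an antigen presentation gene, had 102 ± 27.6 CPM in Kmo_AngII and 41.1 ± 16.4 in AngII (SD, n = 3), a log2 difference of 1.31 ± 0.35 (SE). The macrophage gene Ms4a7 differed by 1.27 ± 0.35, the T cell gene Cd8b1 by 2.06 ± 0.53 and the cytokine gene Il33 by 2.57 ± 0.80, all with an edgeR adjusted p of 0.9998. In Kmo_AngII and AngII, Ms4a7 had 3.69 ± 1.74 and 1.53 ± 0.189 CPM (SD, n = 3). Il33 had 14.7 ± 19.0 and 2.46 ± 0.701, and Cd8b1 only 0.637 ± 0.0990 and 0.152 ± 0.0411, near the floor. Il33 differed by 0.58 without Kmo_AngII replicate 3, and Ms4a7 by 0.81 without Kmo_AngII replicate 2. The mitochondrially encoded list was higher in Kmo_AngII (13 of 13 positive, median 0.88, adjusted p = 7.37e-07; adjusted p = 0.868 with an estimated correlation), although the mean level of Kmo_AngII replicate 1 (-0.61) lay below that of AngII replicate 2 (-0.23). The extracellular matrix and fibroblast lists were also called higher (adjusted p = 6.1e-07 and 2.46e-05; adjusted p = 0.868 for both with an estimated correlation), but both had adjusted p = 0.854 without Kmo_AngII replicate 3. That library also had the highest epicardial (3.59) and atrial (2.83) levels, and Kmo_AngII replicate 2 the highest neutrophil level (3.84). Camera called the endothelial and the blood lists lower (adjusted p = 0.000493 and 0.0054). The first call was lost without Kmo_AngII replicate 1 (0.163) and the second without AngII replicate 1 (0.697), among other alternatives.

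Kmo_AngII minus Ctrl combines both differences. With edgeR, 0 of 19091 genes passed and 533 had an unadjusted p under 0.05 (smallest adjusted p 0.998). DESeq2 called 9 genes, of which Olfr77, Hectd2 and Nmb were higher, and limma-voom called 0. Only Gm49394 passed in edgeR without AngII replicate 1 (adjusted p = 0.0296) or with only those 6 libraries fitted (adjusted p = 0.0265). These 4 genes were chosen after their values were seen. Josd2 differed by -0.01 ± 0.27 on the log2 scale (SE), Atp2a2 by -0.21 ± 0.61, Nppa by 0.31 ± 1.13 and Acta1 by -1.0 ± 1.76, and all 16 index genes had an edgeR adjusted p of 0.998. Of these 4, Josd2 (-0.21 to 0.37), Atp2a2 (-1.07 to 0.23) and Nppa (-0.19 to 1.16) changed sign over the alternatives, and Acta1 ranged from -4.13 (without Kmo_AngII replicate 1) to -0.43 (library size as the only scaling). Macrophage and monocyte markers (25 of 26 positive, median 0.60) and T and NK cell markers (17 of 20 positive, median 0.85) were called higher in Kmo_AngII, each with a camera adjusted p of 5.42e-07. The macrophage call was carried by Kmo_AngII replicates 2 and 3 (mean levels 0.68 and 0.91), since replicate 1, at -0.32, lay below Ctrl replicates 1 and 3 (0.03 and -0.24). The T and NK cell levels were 0.73 to 0.76 in Kmo_AngII and at most 0.60 in Ctrl. The heat shock list was lower, with 0 of 17 genes positive and a median of -0.46 (adjusted p = 5.09e-05), and the antigen presentation list was higher (13 of 15 positive, median 0.45, adjusted p = 0.000124). Both overlapped between the groups, since Kmo_AngII replicate 1 (0.49) lay above Ctrl replicate 1 (-0.41) in the heat shock level and Kmo_AngII replicate 2 (0.09) below Ctrl replicate 1 (0.32) in the antigen presentation level. For these 4 lists the adjusted p was 0.864 with an estimated correlation, and 0 members passed in edgeR, over all genes or adjusted over the list alone. Their members with the smallest p were Aif1 (log2 difference 1.39 ± 0.43, SE), Cd8a (2.69 ± 1.02), Dnajb1 (-0.59 ± 0.21) and H2-K1 (0.82 ± 0.33), each with an edgeR adjusted p of 0.998. Camera called 18 lists here, 7 higher and 11 lower. The lower ones include nuclear oxidative phosphorylation (adjusted p = 8.46e-07), glycolysis (5.56e-06), fatty acid oxidation (0.000105) and sarcomere (0.000124). Without Kmo_AngII replicate 3 these calls were lost (0.794, 0.0709, 0.449 and 0.805), and with an estimated correlation 0 lists were called.

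The title letters divide the same 6 Ctrl and AngII libraries in another way, and this second grouping was fixed before the data were examined. WA minus WC in the fit of all 9 libraries called 0 of 19091 genes with edgeR, with 3443 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0989. DESeq2 called 505 genes (240 higher and 265 lower) and limma-voom 0. In edgeR, 1576 genes passed without Kmo_AngII replicate 1 (927 higher and 649 lower). A single gene passed without Ctrl replicate 1 (Gm10774), without Ctrl replicate 2 (Gm43302) and without AngII replicate 2 (Tent5c), genes named after their values were seen. Fitting only the WA and WC libraries, as fixed in advance for comparison, called 2409 of 18111 genes, 1459 higher and 950 lower in WA, and 5386 had an unadjusted p under 0.05. The common dispersion was 0.0880 in that fit and 0.156 with all 9 libraries. With the treatment label as a covariate 1861 genes passed (1168 higher and 693 lower). The count depended on single libraries, with 459 genes without AngII replicate 2, 524 without Ctrl replicate 3, 1020 without Ctrl replicate 1 and 1270 without Ctrl replicate 2. Library size as the only scaling called 232 genes, 62 higher and 170 lower, and shifted the median of all genes from -0.01 to -0.32.

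In the fit of these 6 libraries, Acta1 (ENSMUSG00000031972) rose most in WA among the genes that the naming rule selects. It had 660.5 ± 37.6 CPM in WA and 13.4 ± 3.47 in WC (SD, n = 3), a log2 difference of 5.63 ± 0.27 (SE; edgeR adjusted p = 3.15e-06). Nppb (ENSMUSG00000029019) had 370.3 ± 95.8 and 36.6 ± 16.4, a difference of 3.35 ± 0.35 (adjusted p = 0.00134). Nppa (ENSMUSG00000041616) had 878 ± 315 and 89.7 ± 36.2, a difference of 3.30 ± 0.37 (adjusted p = 0.00171). Ankrd1, which encodes a stretch-responsive muscle protein, had 1174 ± 309 and 111 ± 42.7, a difference of 3.41 ± 0.34 (adjusted p = 0.00111). The other genes among the 10 rises that the rule takes were Aqp8 (15.0-fold), Edn3 (7.45-fold), Thbs4 (7.08-fold), Tnfrsf12a (6.22-fold), Fmod (6.15-fold) and Mrpl53 (5.86-fold). Of these, Fmod lost its call without AngII replicate 1 (adjusted p = 0.0646), AngII replicate 2 (0.0926), Ctrl replicate 2 (0.0540) or Ctrl replicate 3 (0.0753) and in limma-voom (0.145). In the fit of 9 libraries Acta1, Nppb and Nppa each had an adjusted p of 0.224. The fetal and hypertrophy list was higher in WA, with 14 of 23 members called higher and 1 lower (17 and 1 adjusted over the list alone), a median log2 difference of 1.43 and a camera adjusted p of 2.14e-11. It had adjusted p = 0.181 with an estimated correlation and 0.00308 in fry. Rcan1, a calcineurin target, rose 3.51-fold (adjusted p = 0.00134) and Ankrd23 4.82-fold (adjusted p = 0.000661). Myh6 did not pass (0.26 ± 0.34, adjusted p = 0.659), nor did Myh7 (0.76 ± 0.26, adjusted p = 0.0769), which was called without AngII replicate 3 (0.0349) and by DESeq2 (0.00763).

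Part of the calcium handling and sarcomere lists was called higher in WA. Atp2a2 had 2899.7 ± 636 CPM in WA and 1340.2 ± 317 in WC (SD, n = 3), a log2 difference of 1.12 ± 0.29 (SE; edgeR adjusted p = 0.0257). Its call was lost without AngII replicate 2 (adjusted p = 0.123), Ctrl replicate 1 (0.108), Ctrl replicate 2 (0.0575) or Ctrl replicate 3 (0.118), and with library size as the only scaling (0.357). Pln, which encodes the pump's inhibitor phospholamban, rose 1.97-fold (adjusted p = 0.0385). Its call was lost without AngII replicate 1 (0.0578), AngII replicate 2 (0.148), Ctrl replicate 1 (0.110), Ctrl replicate 2 (0.108) or Ctrl replicate 3 (0.154), and with library size as the only scaling (0.466). Josd2 differed by 0.12 ± 0.18 (adjusted p = 0.718), Ryr2 by 0.01 ± 0.23 and Kmo by 0.48 ± 0.53 (adjusted p = 0.590). Of the calcium handling list 11 of 31 genes were called higher and 2 lower (16 and 4 adjusted over the list alone; camera adjusted p = 0.00321; adjusted p = 0.376 with an estimated correlation). Casq2, the calsequestrin of the calcium store, rose 2.89-fold (adjusted p = 0.00376), the sodium-calcium exchanger gene Slc8a1 2.66-fold (0.00391) and Srl 2.96-fold (0.00242), all 3 of which lost their call with library size as the only scaling (0.121, 0.165 and 0.103). The sarcomere list had 14 of 24 members called higher and 0 lower (17 adjusted over the list alone; median 1.14; camera adjusted p = 3.56e-11; adjusted p = 0.334 with an estimated correlation). Actc1, cardiac alpha-actin, rose from 744 ± 153 to 3664 ± 879 CPM (4.97-fold, adjusted p = 0.00242). The skeletal muscle list was higher too, with 4 of 11 members called (4 adjusted over the list alone; camera adjusted p = 0.00321; adjusted p = 0.334 with an estimated correlation), Mybpc2 among them at 4.36-fold (adjusted p = 0.00530). Of its called members, Acta1 and Mybpc2 are also on the fetal and hypertrophy list, so this call is not a separate finding. The atrial marker list was called higher, with 3 of 12 members (Pam, Nppa and Clu; 3 adjusted over the list alone; camera adjusted p = 0.0343; adjusted p = 0.412 with an estimated correlation), and lost its call without Ctrl replicate 2 (0.102), with the filter of at least 1 CPM in 3 libraries (0.0543) and without mitochondrial, haemoglobin and Nppa genes (0.122). The immediate-early list was called higher too, with 5 of 23 members (5 adjusted over the list alone; camera adjusted p = 0.0394; adjusted p = 0.376 with an estimated correlation), and lost its call without Ctrl replicate 1 (0.0799), without Ctrl replicate 2 (0.0697) and with that filter (0.117). The potassium channel gene Kcnd3 was lower in WA, falling 2.37-fold (adjusted p = 0.00407).

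Camera also called protein folding, proteasome and energy metabolism lists higher in WA. The heat shock list had 14 of 17 genes called higher (14 adjusted over the list alone), a median log2 difference of 1.31 and a camera adjusted p of 2.14e-11 (adjusted p = 0.0958 with an estimated correlation; fry 0.00196). Hspb1 rose 3.40-fold (edgeR adjusted p = 0.00336). Hspa1a rose 4.67-fold (adjusted p = 0.00395), although it shares nearly identical sequence with Hspa1b, which makes its value uncertain. Of the unfolded protein response list 15 of 25 genes were higher (16 adjusted over the list alone; adjusted p = 7.96e-08), including Manf (2.89-fold) and the chaperone gene Hspa5 (2.83-fold). The proteasome and muscle ubiquitin ligase list had 15 of 28 higher (21 adjusted over the list alone; adjusted p = 7.54e-09), including Psma1 (2.13-fold). Nuclear genes of oxidative phosphorylation were higher in 22 of 37 cases (27 adjusted over the list alone; median 0.82; adjusted p = 3.38e-12), including Uqcrc2 (2.5-fold). Fatty acid oxidation genes were higher in 20 of 34 cases and lower in 1 (23 and 1 adjusted over the list alone; adjusted p = 7.66e-10), including Fabp3 (2.84-fold). These 4 lists had adjusted p = 0.376 with an estimated correlation. With library size as the only scaling Manf (0.0963), Hspa5 (0.109), Psma1 (0.319), Uqcrc2 (0.209) and Fabp3 (0.128) lost their calls. The glycolysis list was higher as a whole (10 of 25 higher, 1 lower; 12 and 1 adjusted over the list alone; adjusted p = 6.98e-05; adjusted p = 0.412 with an estimated correlation), but Pfkfb1 fell 3.94-fold (adjusted p = 0.00134). The mitochondrially encoded list was not called (median 0.54, adjusted p = 0.251). Among 62 deubiquitinases 12 were higher and 5 lower, and the list was not called (adjusted p = 0.185).

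Matrix genes were partly higher in WA. Of 43 extracellular matrix genes 15 were called higher and 1 lower (20 and 2 adjusted over the list alone; median log2 difference 0.72; camera adjusted p = 2.3e-05; adjusted p = 0.383 with an estimated correlation; fry 0.0540). Ccn2, a connective tissue growth factor, rose 3.54-fold (edgeR adjusted p = 0.00223), Cilp 4.0-fold (0.00242) and Ltbp2 5.33-fold (0.00336). Postn, which encodes periostin, rose 3.57-fold (adjusted p = 0.0139; 0.0743 without AngII replicate 2). Col3a1 rose 1.91-fold (adjusted p = 0.0234; lost at 0.113 without AngII replicate 2, 0.0580 without Ctrl replicate 1, 0.0848 without Ctrl replicate 2 and 0.404 with library size as the only scaling). Timp1 rose 2.73-fold (adjusted p = 0.0208; lost at 0.0990 without AngII replicate 2, 0.0565 without Ctrl replicate 1, 0.0816 without Ctrl replicate 2, 0.107 without Ctrl replicate 3 and 0.247 with library size as the only scaling). Col1a1 did not pass (0.72 ± 0.32, SE; adjusted p = 0.163). The myofibroblast markers were higher in 5 of 12 cases (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00296; adjusted p = 0.376 with an estimated correlation), whereas the fibroblast markers were not called (adjusted p = 0.0687). Thbs4, Col8a1 and Cilp are on both the matrix and the myofibroblast list. Agtr1a, the angiotensin receptor gene, differed by 0.17 ± 1.16, and the renin-angiotensin list was not called (adjusted p = 0.691).

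Camera called 7 lists lower in WA, of blood, endothelial, Schwann cell and 4 immune cell markers. Haemoglobin genes took 0.0279% ± 0.0118 of the counts in WA and 0.645% ± 0.323 in WC (SD, n = 3; two-sided exact permutation p = 0.1, the smallest possible). The blood and erythroid list had 8 of 10 genes called lower (9 adjusted over the list alone), a median log2 difference of -4.07 and a camera adjusted p of 3.47e-07 (adjusted p = 0.376 with an estimated correlation). Hbb-bs fell 14.7-fold (edgeR adjusted p = 0.00697), and the platelet gene Ppbp fell 15.4-fold, from 5.38 ± 1.80 to 0.345 ± 0.118 CPM (adjusted p = 0.000982). Hba-a1 fell 17.8-fold (adjusted p = 0.0111) but lost its call without AngII replicate 1 (0.0507) or Ctrl replicate 3 (0.0502). Hba-a2 fell 17.1-fold and did likewise (0.0538 and 0.0502). Hbb-bt fell 16.5-fold (adjusted p = 0.0119; 0.0618 without Ctrl replicate 3 and 0.0511 without a low-count filter). Tent5c fell 10.5-fold (adjusted p = 0.00739; 0.0577 without Ctrl replicate 3 and 0.0700 in limma-voom), and Acss3 fell 7.58-fold (adjusted p = 0.00391). Alas2 fell 14.3-fold (adjusted p = 0.0480) but lost its call without AngII replicate 1 (0.124), AngII replicate 2 (0.0810), Ctrl replicate 1 (0.125), Ctrl replicate 2 (0.0557) or Ctrl replicate 3 (0.158), with DESeq2 size factors (0.0502) and without a low-count filter (0.0937). Slc4a1, which lay near 0 in WA, was also called lower (adjusted p = 0.0434) and lost its call without AngII replicate 3 (0.112), Ctrl replicate 1 (0.108), Ctrl replicate 2 (0.131) or Ctrl replicate 3 (0.167), with library size as the only scaling (0.165), without a low-count filter (0.0961) and in limma-voom (0.382). The alpha and beta haemoglobin copies share nearly identical sequence, so their values are uncertain one by one. Neutrophil markers were lower in 5 of 10 cases (10 adjusted over the list alone; median -3.43; camera adjusted p = 1.8e-05; adjusted p = 0.408 with an estimated correlation), with Csf3r 3.90-fold lower (adjusted p = 0.00442). Endothelial markers were lower in 2 of 20 cases (5 adjusted over the list alone; camera adjusted p = 0.00224; adjusted p = 0.376 with an estimated correlation), Vwf among them at 2.52-fold (adjusted p = 0.00678). The other 4 calls were lost without AngII replicate 3 (adjusted p from 0.0614 to 0.125), the T and NK cell call also without Ctrl replicate 1 (0.0558), the Schwann cell call also with the filter of at least 1 CPM in 3 libraries (0.0592), and the B and plasma cell call also with that filter (0.0754) and without AngII replicate 2 (0.111), Ctrl replicate 1 (0.142) or Ctrl replicate 3 (0.0517). They were the macrophage and monocyte list (3 of 26 genes lower, also adjusted over the list alone; adjusted p = 0.00901; adjusted p = 0.383 with an estimated correlation), the T and NK cell list (1 of 18 lower, 0 adjusted over the list alone; adjusted p = 0.0213; adjusted p = 0.572 with an estimated correlation), the B and plasma cell list (1 of 14 lower, also adjusted over the list alone; adjusted p = 0.0352; adjusted p = 0.572 with an estimated correlation) and the Schwann cell and neuron list (2 of 10 lower, also adjusted over the list alone; adjusted p = 0.00901; adjusted p = 0.334 with an estimated correlation).

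**Figure D3:**
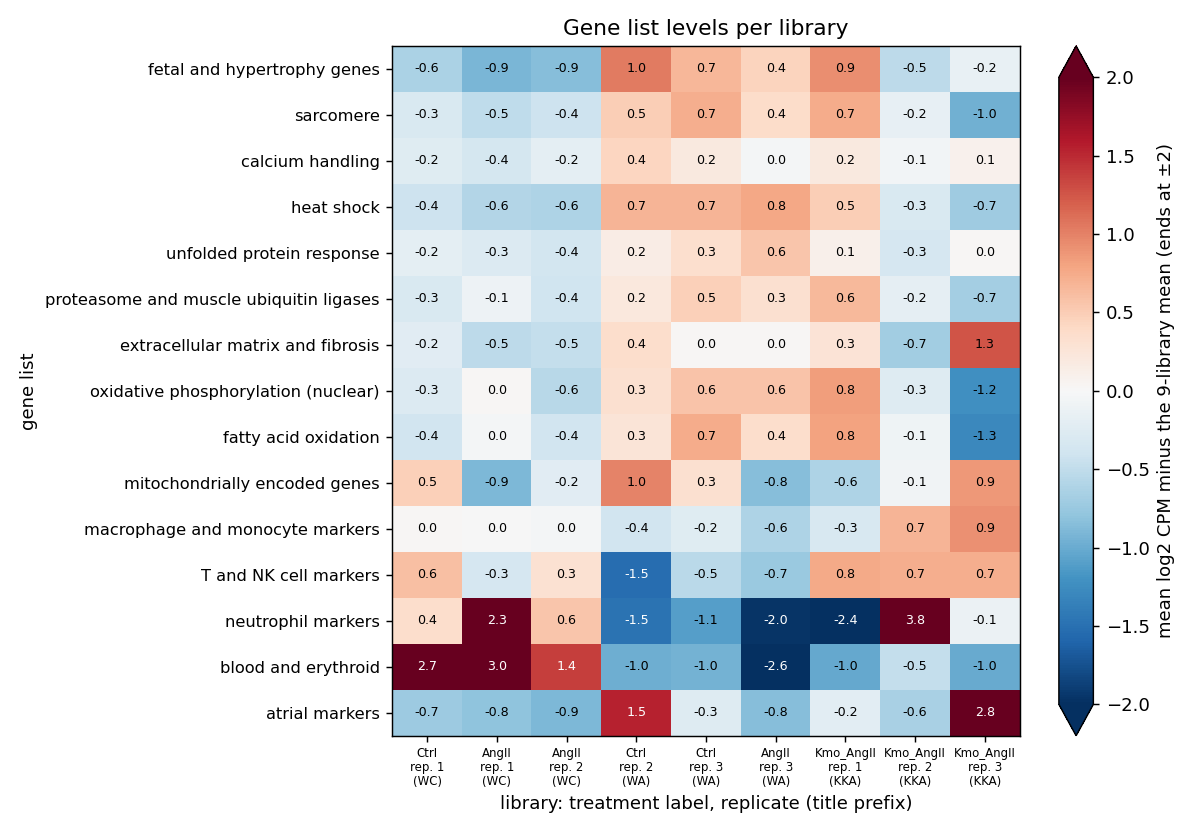
Mean log2 CPM of the genes of 15 lists in each of the 9 libraries, relative to the mean of the list over the 9 libraries (colour scale ends at -2 and 2). The libraries are ordered by title prefix, and the fetal and hypertrophy, sarcomere and heat shock lists are above 0 in the 3 WA libraries and Kmo_AngII replicate 1.

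The KKA libraries are the same 3 libraries as Kmo_AngII and were compared with WA and WC in the fit of 9 libraries. KKA minus WA called 0 genes with edgeR (1345 at an unadjusted p under 0.05), 91 with DESeq2 (81 higher and 10 lower) and 0 with limma-voom. Without Kmo_AngII replicate 1 edgeR called 1709 genes (794 higher and 915 lower), among them Acta1 (log2 difference -4.65, adjusted p = 0.00656) and Atp2a2 (-1.31, adjusted p = 0.0463). It called 3 without Kmo_AngII replicate 3 (Gm15446, Dcp1a and Cyp26b1) and 1 without Ctrl replicate 2 (Gm43302). KKA minus WC called 0 genes with edgeR (671 at an unadjusted p under 0.05), 27 with DESeq2 and 0 with limma-voom. It called 7 without Kmo_AngII replicate 2, including Thbs4, Cilp and Nppa, 3 without AngII replicate 3 (Hba-a1, Hba-a2 and Alas2), 2 without Kmo_AngII replicate 3 (Gm15446 and Dcp1a), and 1 without Ctrl replicate 1 (Gm10774) or AngII replicate 2 (Tent5c). The genes named for these counts were chosen after their values were seen. Relative to WA, camera called the T and NK cell markers higher (20 of 20 positive, median 1.22, adjusted p = 8e-11; 6 called adjusted over the list alone; adjusted p = 0.419 with an estimated correlation). Macrophage and monocyte markers were also called higher, although Kmo_AngII replicate 1 (-0.32) lay below Ctrl replicate 3 (-0.24) in their mean level (26 of 26 positive, median 0.85, adjusted p = 2.8e-10; 6 adjusted over the list alone; adjusted p = 0.623 with an estimated correlation). Heat shock genes were lower (median -0.74, adjusted p = 1.29e-12; 3 adjusted over the list alone; adjusted p = 0.419 with an estimated correlation). Relative to WC, blood and erythroid genes were lower (median -3.68, adjusted p = 6.67e-23; 9 adjusted over the list alone; adjusted p = 0.303 with an estimated correlation).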

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

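Alternatives for WA minus WC in 6 libraries were chosen after that result was seen, and the others were planned. No named gene was called in both directions, and of 5596 recomputed values of named genes 5296 stayed on their side of the threshold, 265 lost a call and 35 gained one, while 135 uncalled values changed sign, so the direction of an uncalled gene is not settled. Of the called lists 1 was also called in the other direction: nuclear oxidative phosphorylation in Kmo_AngII minus AngII was lower (camera adjusted p = 0.00523) but higher without Kmo_AngII replicate 3 (0.0144). The cause of each changed count was not tested, except that leaving out libraries leaves fewer samples.

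With library size as the only scaling, edgeR called 11 genes in WA minus WC over 9 libraries (0 higher, 11 lower), 1 in KKA minus WA (Cyp26b1), 7 in KKA minus WC (0 higher, 7 lower) and 232 in WA minus WC over 6 libraries, and camera called 19 lists in AngII minus Ctrl, where 8 were called with TMM. That scaling moved the median log2 difference of all genes to 0.67 in AngII minus Ctrl, -0.29 in Kmo_AngII minus AngII, 0.37 in Kmo_AngII minus Ctrl, 0.16 in KKA minus WA, -0.13 in KKA minus WC and -0.33 in WA minus WC over 9 libraries, where TMM left it between -0.03 and 0.05. Without a low-count filter edgeR called 5 genes in WA minus WC (Hba-a1, Hba-a2, Hbb-bs, Hbb-bt and Tent5c), 1 in KKA minus WA (Cyp26b1) and 4 in KKA minus WC (Hba-a1, Hba-a2, Hbb-bs and Tent5c). These genes were chosen after their values were seen.

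The DESeq2 Wald test called 2 genes in AngII minus Ctrl, 3 in Kmo_AngII minus AngII, 9 in Kmo_AngII minus Ctrl, 505 in WA minus WC, 91 in KKA minus WA and 27 in KKA minus WC, where edgeR and limma-voom called 0 in each. Fitting only the groups compared called 1 gene in Kmo_AngII minus Ctrl and 2409 in WA minus WC, and 14 lists in AngII minus Ctrl. With the treatment label as a covariate 1861 genes were called in WA minus WC. With an estimated correlation camera called 0 lists in each comparison, from 8 in AngII minus Ctrl, 14 in Kmo_AngII minus AngII, 18 in Kmo_AngII minus Ctrl, 17 in WA minus WC, 14 in KKA minus WA, 13 in KKA minus WC and 21 in WA minus WC over 6 libraries. Fry called 0 in the first 6 of these and 12 in the last (11 higher, 1 lower).

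Leaving out each library in turn gave 0 to 1 genes in AngII minus Ctrl, Kmo_AngII minus AngII and Kmo_AngII minus Ctrl. It gave 0 to 1576 in WA minus WC and 0 to 1709 in KKA minus WA (both highest without Kmo_AngII replicate 1), 0 to 7 in KKA minus WC (highest without Kmo_AngII replicate 2), and 459 to 2980 in WA minus WC over 6 libraries (without AngII replicate 2 and AngII replicate 3). Called lists ranged from 4 to 16 in AngII minus Ctrl (without AngII replicate 2 and AngII replicate 3), 13 to 23 in Kmo_AngII minus AngII (23 without Kmo_AngII replicate 1), 12 to 23 in Kmo_AngII minus Ctrl (without Ctrl replicate 3 and Kmo_AngII replicate 2), 15 to 21 in WA minus WC, 14 to 21 in KKA minus WA (21 without Kmo_AngII replicate 2), 13 to 22 in KKA minus WC (22 without Kmo_AngII replicate 1), and 19 to 27 in WA minus WC over 6 libraries.

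Lists called under each of the alternatives run with the preset correlation (10 to 16 per list: scalings, filters, groups fitted, covariates and left-out libraries) numbered 1 of 8 in AngII minus Ctrl, 5 of 14 in Kmo_AngII minus AngII, 4 of 18 in Kmo_AngII minus Ctrl, 11 of 17 in WA minus WC, 11 of 14 in KKA minus WA, 2 of 13 in KKA minus WC and 15 of 21 in WA minus WC over 6 libraries.

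In WA minus WC over 6 libraries, the rule takes 20 genes by size, from called genes of at least 1 mean log2 CPM without overlap. They kept their direction in every refit that tested them, and 13 were still called without Ctrl replicate 3. The kept direction is no support, because leaving out a library can hardly reverse a gene selected for having no overlap. Of the 119 named and called genes 42 were still called with library size as the only scaling, 113 with limma-voom, 66 without AngII replicate 2 and 72 without Ctrl replicate 3. No paired analysis was possible because replicate numbers were given in sample order and no label ties libraries of different groups together.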

Other observations

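The tests of explanations below were chosen after the results were seen, 2 of them in place of earlier tests on the single genes Myh6 and Acta1, and the counts of other splits were fixed by the design. Genes named here outside the naming rule were chosen after their values were seen. The library labelled Kmo_AngII replicate 3 held the highest levels of atrial genes. Myl7, the atrial light chain, had 469 CPM there and at most 47.7 in any other library, Sln 289 and 35.0, Myl4 385 and 65.2, and Bmp10 41.3 and 0.0717. The library labelled Ctrl replicate 2, titled WA, gave these next highest values of Myl7, Sln and Myl4 and also stood apart, since in the other 7 libraries Myl7 was at most 0.854, Sln 0.488 and Myl4 2.89. The ventricular light chain gene Myl2, at 1663 in Kmo_AngII replicate 3, was lowest there among the 9 libraries. The same library had the highest Col1a1 (198 CPM), Col3a1 (317) and Timp1 (14.9). Its mean levels were also the highest of the 9 libraries for the epicardial (3.59), Schwann cell (1.97), adipocyte (1.69) and endocardial (1.25) lists. Its sarcomere level (-0.96) was the lowest. The neutrophil genes S100a8 and S100a9 were highest in the libraries labelled Kmo_AngII replicate 2 (85.1 and 129 CPM) and AngII replicate 1 (51.6 and 68.5), and S100a8 was at most 7.19 in the other libraries. Agtr1a was 0.860 in the library labelled AngII replicate 1 and between 10.1 and 22.2 in the other libraries.

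The atrial genes in Kmo_AngII replicate 3 may come from atrial tissue in that sample, since the smallest of the 4 folds over the next library was 5.90, for Myl4. A rise of atrial genes together with hypertrophy of heart muscle stays open: the mean level of the hypertrophy list without its 2 atrial markers was -0.53 in that library, against -0.84 to -0.58 in WC and 0.47 to 0.94 in WA. Acta1 (12.98 CPM) and Nppb (23.1) lay within the range of the WC libraries there. Nppa (1101), which is itself on the atrial list, and the matrix gene Postn (74.5) lay within the range of the WA libraries, and Ccn2 (64.1) near it. No label says which part of a heart was taken, and no biological explanation tied to the group was tested.

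The hypertrophy genes were divided by the title prefix more than by the treatment label. Of the 24 genes of the list 16 were higher in every WA library than in every WC library and 1 the other way, where chance gives 5% per direction. By label, 1 was higher in every AngII than in every Ctrl library and 2 the other way. The share over all tested genes was not computed. In the fit of the 6 WA and WC libraries 5386 of 18111 genes had an unadjusted p under 0.05, so the 5% does not show what is particular to this list. Within each prefix the mean level of the list was lower in AngII than in Ctrl. In WC it was -0.91 and -0.86 in AngII replicates 1 and 2, against -0.63 in Ctrl replicate 1. In WA it was 0.44 in AngII replicate 3, against 1.05 and 0.66 in Ctrl replicates 2 and 3. A candidate explanation is that treatment labels were exchanged between Ctrl and AngII libraries, and another is that the prefix marks a condition that the labels do not give, which was not tested. The prefix cannot be told apart from whatever the title numbers stand for, and a grouping by these numbers was not tested either. The prefix alone does not give the division on the first component, where Kmo_AngII replicate 1 lay with WA and Kmo_AngII replicates 2 and 3 with WC. An exchange would have to leave the measures that divide these libraries as labelled. The mitochondrial share was 43.4% to 52.6% in Ctrl and 30.3% to 39.5% in AngII. The TMM factor and the number of genes above 0 did not overlap either (two-sided exact permutation p = 0.1 for each, the smallest possible). These measures are not independent, since a larger mitochondrial share leaves fewer counts for the other genes, so they are not separate evidence. The exchange stays open. Atrial tissue as the cause in all 3 WA libraries is argued against, because 0 of 4 atrial markers was higher in all WA than in all WC libraries, but the library labelled Ctrl replicate 2 carries an atrial signal (Myl7 47.7 CPM, and 0.399 and 0 in the other WA libraries), and the camera call of the atrial list (adjusted p = 0.0343) was lost without it (0.102). Blood diluting muscle RNA in the WC libraries is argued against, since blood would have to make up 62.9% of their counts for the list's median of 1.43 and haemoglobin genes took at most 0.986%, whereas a lower share of heart muscle for another reason stays open, as the sarcomere list was higher (median 1.14) and the endothelial list lower (median -0.33) in WA, but the matrix list higher (median 0.72). Heart muscle genes did not all move alike in the fit of these 6 libraries. Myh6 (0.26 ± 0.34, SE) and Ryr2 (0.01 ± 0.23) differed little, whereas Atp2a2 (1.12 ± 0.29) and Pln (0.98 ± 0.27) were called higher in WA.

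Mitochondrially encoded genes took a smaller share of the counts in AngII than in Ctrl. Whether the AngII hearts held fewer mitochondria stays open, because transcript levels do not count mitochondria. The nuclear genes of oxidative phosphorylation did not fall with the mitochondrial genes. Their median log2 difference was -0.18 (quartiles -0.51 and 0.07), against -1.36 (quartiles -1.47 and -1.11) for the mitochondrial genes. The mitochondrial ribosomal RNA genes mt-Rnr1 (-0.15 ± 0.45, SE) and mt-Rnr2 (-0.09 ± 0.40) did not fall by that size either, although their recovery may depend on the poly(A) selection. A difference in RNA or library preparation cannot be told apart from the treatment, since no label gives a batch and the exact permutation p of 0.1 is the smallest that 3 against 3 libraries allow. An effect of angiotensin II on mitochondrial transcripts stays open and was not tested.

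Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. AngII minus Ctrl called 0 genes and at most 1 in another split (10 of 10 splits as many), and 8 lists against at most 19 (8 of 10). Kmo_AngII minus AngII called 0 genes against 1 (10 of 10) and 14 lists against 24 (9 of 10). Kmo_AngII minus Ctrl called 0 genes against 1907 (10 of 10) and 18 lists against 22 (8 of 10). The split with 1907 set Ctrl replicates 2 and 3 and Kmo_AngII replicate 1 against the others, which points to a structure of the samples. WA minus WC over 9 libraries called 0 genes against 1 (10 of 10) and 17 lists against 19 (2 of 10). KKA minus WA called 0 genes against 1 (10 of 10) and 14 lists against 24 (10 of 10), and KKA minus WC 0 against 1 (10 of 10) and 13 against 24 (9 of 10). WA minus WC over 6 libraries called 2409 genes against 2 (1 of 10) and 21 lists against 20 (1 of 10).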
